A study of Homo sapiens with 2 samples.

How the data were processed

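Total RNA of DLD1 cells treated with vehicle or with 10 μM PLD1 inhibitor was profiled, per the labels' protocols, with 100 ng of RNA per sample, dephosphorylated, ligated to a Cy3-labelled nucleotide and hybridised to Agilent miRNA arrays of 1 colour. There was 1 array per condition (2 arrays in all), taken from GEO's label for the treatment. Per the file headers, the authors extracted spot intensities with Agilent Feature Extraction 11.5.1.1 under the protocol miRNA_1105_Oct12 for array design 046064, annotated on build hg19. The processed intensity of a spot is its brightness after subtraction of the local background by the authors' software, per the file headers, with no scaling between arrays; it falls below 0 for dim spots (23762 of 60180 miRNA spots of the file labelled vehicle and 23115 of the file labelled inhibitor). The deposited value table holds log2 values: each equals log2 of Feature Extraction's total gene signal, floored at 0.1, without scaling or centring between arrays (the median of both columns is -3.32, the floor). Its scale was settled by this match, but the columns of the 2 samples are crossed relative to the scanner files, and which of the sources carries the right labels stays unknown. Groups were taken from the labels of the scanner files. The header and statistics blocks of both scanner files are the same, and the number of spots well above background they state, 11411, is that of the vehicle file. Slide and scan could therefore not be read for the inhibitor file, and neither was tested as a batch. The x positions of the spots ran from 682.5 to 4144.2 in the vehicle file and from 5972.5 to 9434.3 in the inhibitor file. The arrays thus had different positions, which cannot be told apart from the condition.

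The main setting was log2 of the processed signal relative to each array's 75th percentile over the probes detected on both arrays (681 probes), which was a signal of 368.3 for the vehicle file and 289.1 for the inhibitor file, a scale factor of -0.35 on the log2 scale. Control spots and spots with an outlier flag were left out (1383 and 1157 miRNA spots, 2.30% and 1.92%). The floor of 1 signal unit was set after scaling; it touched 0 spots of the probes detected on both arrays. Spots of a probe were averaged on the log2 scale. A probe counted as detected when at least 50% of its usable spots were flagged well above background, and a miRNA when at least 1 of its probes was. The level of a miRNA is the mean over its probes detected on both arrays; of 296 miRNAs with several such probes, the probes of 29 differed in sign, and the median range between probes was 0.073 on the log2 scale. The lowest mean signal of a detected probe was 15.7 for the vehicle file and 15.9 for the inhibitor file, against a mean of 1.96 ± 3.35 and 3.70 ± 3.59 (SD over spots) of the negative controls. With 1 array per condition no test was run. The standard error given is that between spots; the number of arrays limits the precision of every comparison.

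miRNA names are those of the scanner files. Genomic neighbours were taken by gene symbol from the RefSeq gene table of GRCh38.p14, which matched 323 of the 365 miRNAs detected on both arrays to 1 gene, 27 to several and 15 to none; as the array is annotated on another build, no coordinates are given. The miRNA lists were written from general knowledge before the data were examined, and a list takes every mature arm of its members. A list's median is set against 10000 random lists of the same size, drawn with replacement within 5 bins of mean signal, as a description of these 2 arrays.

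The text names, by a rule fixed at the same time, miR-4496; the 12 miRNAs with the largest differences each way among those at least 2-fold apart by over 3 standard errors between spots; the 4 largest bounds each way; in each list the 2 brightest members and the 2 with the largest differences; and the 5 brightest miRNAs. miR-194-5p, miR-10b-3p, miR-135a-3p and miR-200a-5p are named outside this rule, chosen after their values were seen, as further members of their lists, and the closing observations name further miRNAs chosen in the same way. The procedure was tested on simulated data, spots of the 365 miRNAs with 200 of these changed by log2 1.5 or 2 in either direction. After the median shift of the unchanged miRNAs was removed, 100% of the changed miRNAs passed 2-fold and 0 of the 165 unchanged ones did, with a largest error of 0.90. Both simulated arrays were drawn from the probe means of the vehicle file, with a capped spread of spots and only a common factor between them. The outcome therefore checks the calculation. It gives no rate of missed or false differences between 2 separate arrays. Alternatives were the other scalings (75th percentile of all probes, median, quantile normalization, none), stricter and no detection filters, the brightest probe of a miRNA, the total gene signal and the deposited value table. The planned normexp background correction on the mean signal was replaced, after the files were seen, by normexp with an offset of 50 on the median signal, since no mean signal was among the columns; the value table with its columns matched to the scanner files was also added then. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.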

Results

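miRNA levels were measured in DLD1, an established human colorectal adenocarcinoma cell line with active Wnt signalling, after 36 h in medium with 1% heat-inactivated serum, with vehicle or with 10 μM of an inhibitor of phospholipase D1 (PLD1), the enzyme that makes phosphatidic acid from phosphatidylcholine. Each condition was represented by 1 Cy3-labelled Agilent human miRNA array, so differences between the conditions have no replicate check and no p-value is given; each error below is a standard error from the spread of spots within the arrays and covers measurement only. Each array carried 60180 miRNA spots for 2006 human miRNAs, measured through 4774 probes. The array deposited as vehicle had 11411 miRNA spots well above background (19.0%) and 427 detected miRNAs, and the array deposited as inhibitor had 10133 such spots (16.8%) and 380 detected miRNAs. A total of 365 miRNAs were detected on both arrays, 77 on 1 array only and 1564 on neither. No miRNA spot was saturated. The 5 brightest miRNAs on both arrays were miR-4454, miR-6087, miR-6089, miR-4516 and miR-5100, with mean processed signals of 229738, 33627, 13170, 11733 and 12714 on the array deposited as vehicle.

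The deposited sources did not settle which array belongs to which condition. The value table that accompanies the series holds the log2 total signal of each miRNA, and its vehicle column equalled the scanner file labelled inhibitor for 2006 of 2006 miRNAs (largest gap 4.77e-09), while its inhibitor column equalled the scanner file labelled vehicle for 2006 of 2006 (largest gap 4.97e-09). Both scanner files also carried the same header, whose statistics match the spots of the vehicle file only. The arrays are therefore called the vehicle-file array and the inhibitor-file array here, and signs are inhibitor-file minus vehicle-file. With the labels of the value table put on the same scaled values every one of these signs turns, so that "higher on the inhibitor-file array" reads "lower with PLD1 inhibitor".

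The first comparison concerns miR-4496, which the study is known to have followed as a miRNA raised by PLD1 inhibition and acting on β-catenin. Among the miRNAs detected on both arrays its difference, 6.02-fold, was the largest in this setting, ahead of miR-4497 by less than its error, with a mean signal of 120.8 on the vehicle-file array and 16.2 on the inhibitor-file array (log2 difference -2.59 ± 0.11 between spots). By the labels of the scanner files miR-4496 was lower with the inhibitor, opposite to the study's account; by the labels of the value table it was higher, with a log2 difference of 2.92 in that unscaled table. All 3 of its probes went the same way, with log2 differences of -2.54, -2.73 and -2.64. On the dimmer array 60%, 30% and 50% of the spots of these probes were well above background, and 1 of the probes had the lowest signal of any probe counted as detected there, 15.9, so that level lay at the detection limit. When every spot had to be well above background, the miR-4496 difference was a bound of -2.25 on the log2 scale, and under the normexp background correction the difference was -0.91, at rank 17 by size. It ranked behind miR-4497 with quantile normalization and with the brightest probe of each miRNA, at rank 3 behind miR-135a-3p with the scaled total gene signal and with the value table matched to the scanner files, and at rank 5 without a detection filter.

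**Figure D1:**
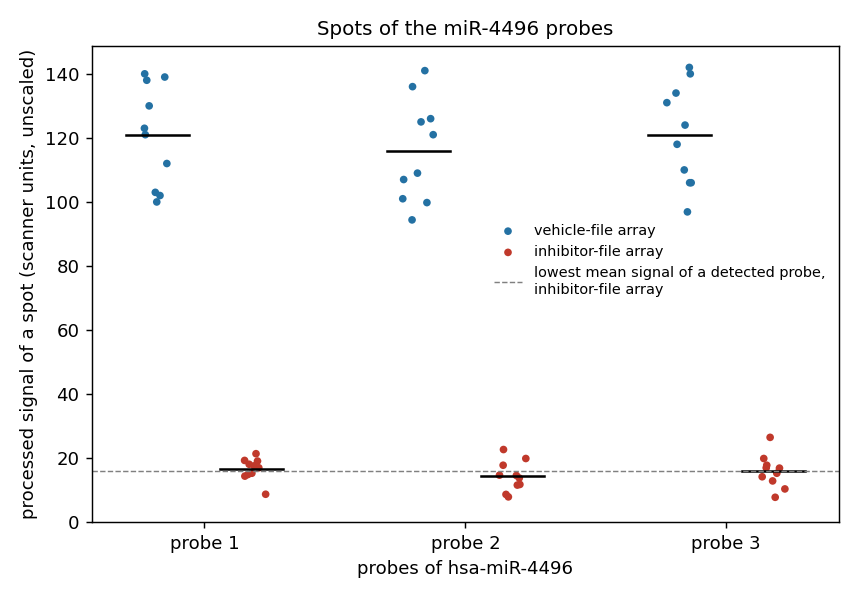
Processed signal of each usable spot (scanner units, not scaled) for the 3 probes of miR-4496 on the vehicle-file array (blue) and the inhibitor-file array (red); black bars are means over spots and the dashed line is the lowest mean signal of a probe counted as detected on the inhibitor-file array. The probe means were 120.8, 116.0 and 120.8 on the vehicle-file array and 16.6, 14.4 and 15.9 on the inhibitor-file array.

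Among the 365 miRNAs detected on both arrays, 17 were at least 2-fold higher and 19 at least 2-fold lower on the inhibitor-file array. The largest higher signal was that of miR-10a-3p, the minor arm of a miRNA of the HOXB cluster, at 3.54-fold (log2 difference 1.82 ± 0.059). It was followed by miR-21-3p, the minor arm of the oncogenic miR-21, at 3.44-fold (1.78 ± 0.036), and by miR-7-5p, known for repressing the EGF receptor, at 3.21-fold (1.68 ± 0.039). miR-21-3p is the partner of miR-21-5p, with a difference of 0.58 ± 0.022, and miR-10a-3p that of miR-10a-5p, with a difference of 0.54 ± 0.019. Next came miR-3934-5p (2.64-fold), miR-29b-1-5p (2.52-fold, from 1 probe), miR-221-3p (2.39-fold), a repressor of the cell cycle inhibitor p27, miR-196b-5p (2.38-fold), which lies in the HOXA cluster, miR-622 (2.32-fold) and miR-3135b (2.25-fold). The 12 largest were completed by miR-18a-5p (2.19-fold), miR-5585-3p (2.16-fold) and miR-17-5p (2.12-fold).

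Of the 12 largest lower signals, miR-4497 came closest to miR-4496, with a 5.87-fold lower signal on the inhibitor-file array (841.5 against 110.9, log2 difference -2.55 ± 0.041). The next was miR-320a, reported to target β-catenin, at 3.12-fold lower (-1.64 ± 0.022). They were followed by miR-630 (2.82-fold lower), miR-4459 (2.73-fold), miR-513a-5p (2.67-fold), miR-575 (2.65-fold), miR-1246 (2.62-fold), miR-6126 (2.52-fold), miR-5787 (2.51-fold), miR-1290 (2.43-fold, from 1 probe) and miR-4530 (2.40-fold). The sequence annotated as miR-1246 is known to occur in the U2 small nuclear RNA, so its probe can also report fragments of that RNA.

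All 36 differences of at least 2-fold exceeded 3 times their standard error between spots, and none had probes of opposite sign. With a median standard error of 0.034 this mark is easily passed, and 298 of all 365 miRNAs passed it. It therefore does not single out the 36. Comparing alternate spots of the same array gave 0 of 365 miRNAs at least 2-fold apart on either array, with a largest gap of 0.46 on the log2 scale, so the differences exceeded the measurement error within an array; variation between cultures or labelling reactions was not measured. The split between higher and lower depended on the scaling: it was 19 and 13 with the median of the detected probes, 11 and 22 with the 75th percentile of all probes, and 4 and 40 without scaling, which moved the median of all 365 differences to -0.35. The normexp background correction, which compresses dim signals, left 4 and 5.

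Detection on a single array was uneven: 62 miRNAs were detected on the vehicle-file array only and 15 on the inhibitor-file array only. Spots were flagged before scaling, and the vehicle-file array was brighter at the 75th percentile of the probes detected on both arrays (368.3 against 289.1). The 2 counts therefore do not separate brightness of an array from its miRNA content. The largest bounds were those of miR-1287, at least 7.09-fold higher on the vehicle-file array (136.8 against 12.4), miR-658 (at least 3.68-fold), miR-424-3p (at least 3.27-fold, from 1 probe) and miR-5703 (at least 2.79-fold). In the other direction the largest were miR-193a-3p, at least 2.10-fold higher on the inhibitor-file array (25.1 against 15.2), miR-149-5p (at least 1.92-fold), miR-16-2-3p (at least 1.86-fold) and miR-141-5p (at least 1.77-fold), each from 1 probe. A bound reached 2-fold for 7 of the 62 and 1 of the 15, and for 13 of the 62 it stayed under 1, so that no fold is given. Each bound is the brighter level over the higher of the other array's dimmest detected signal and the probe's own signal there.

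**Figure D2:**
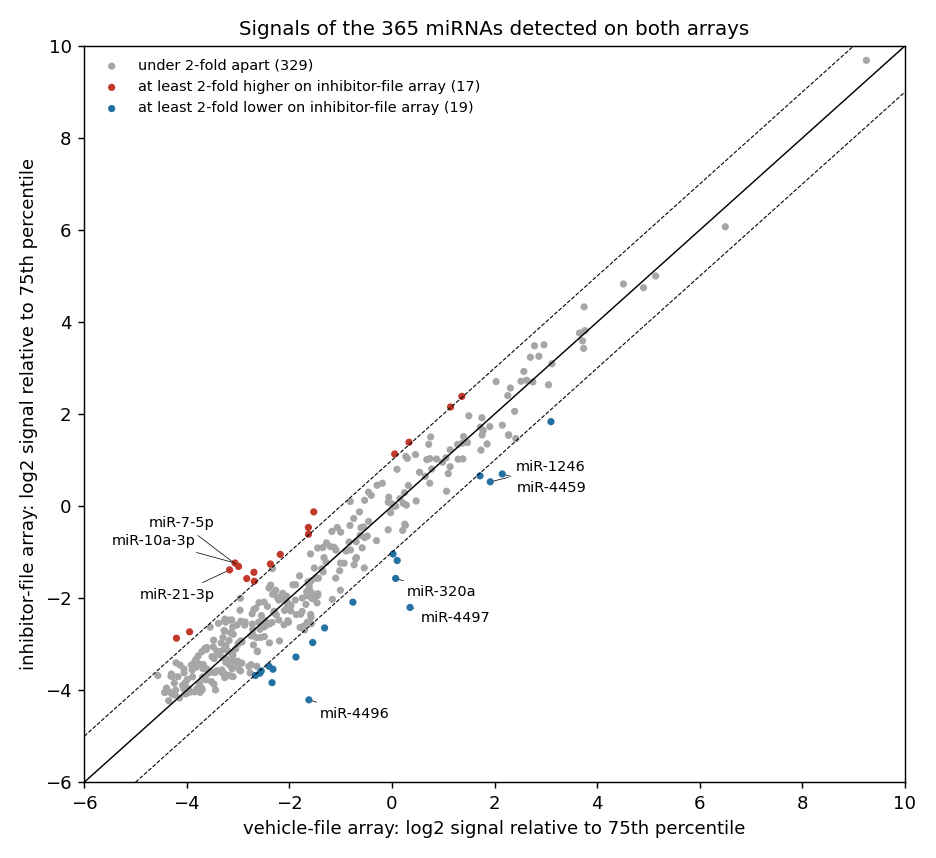
Signal of each of the 365 miRNAs detected on both arrays, as log2 of the processed signal relative to the array's 75th percentile, on the vehicle-file array (x axis) and the inhibitor-file array (y axis), 1 array each; the solid line marks equal levels and dashed lines 2-fold differences. The 17 red and 19 blue points are the miRNAs at least 2-fold higher and lower on the inhibitor-file array, with miR-4496 and miR-4497 farthest below the line.

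The gene groups were examined next. The clearest group was the miR-17-92 cluster with its paralogs, E2F- and MYC-driven miRNAs that promote proliferation. All 12 of its members detected on both arrays were higher on the inhibitor-file array, by 0.64 to 1.13 on the log2 scale, with a median of 1.01. By the main scaling 7 of the 12 were at least 2-fold higher, at 1.01 to 1.13. That count depends on the scaling, since the list median was 0.92 with the 75th percentile of all probes and 0.67 without scaling. Its brightest members were miR-19b-3p, 2.03-fold higher (1.02 ± 0.018), and miR-20a-5p, 2.02-fold higher (1.01 ± 0.026), and its largest differences were those of miR-18a-5p and miR-17-5p. Of 10000 random lists matched on signal, 95% had medians between -0.33 and 0.38. The random lists were not matched on miRNA number, and all 12 members are numbered up to 1000, a class with a median of 0.21. The list median stayed between 0.67 and 1.09 under all 10 alternatives that keep the scanner labels, none of which scaled the arrays on control probes.

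3 smaller groups also lay above the range of 95% of random lists. The upper ends of these ranges were 0.61, 0.60 and 0.62 for the miR-15/16, miR-29 and HOX cluster lists. The members of all 3 groups are numbered up to 1000, a class with a median of 0.21 to which the random lists were not matched. Random lists within that class were not drawn, so whether these groups stand out from it stays open. All 4 members of the miR-15/16 family detected on both arrays were higher on the inhibitor-file array (median 0.71). Among them were miR-16-5p (0.75 ± 0.020), miR-15b-5p (0.66 ± 0.026) and miR-424-5p (0.77 ± 0.058, from 1 probe), of a family which restrains cyclins and BCL2. The list also takes the opposite arms. Of these miR-424-3p went the other way, detected on the vehicle-file array only and at least 3.27-fold higher there, by 1 probe. The arm miR-16-2-3p was detected on the inhibitor-file array only. All 4 members of the miR-29 list detected on both arrays were higher (median 0.68). They were miR-29a-3p (0.54 ± 0.022), miR-29b-3p (0.68 ± 0.014) and miR-29c-3p (0.69 ± 0.016), repressors of collagens and DNA methyltransferases. The fourth was the opposite arm miR-29b-1-5p (1.33 ± 0.081, from 1 probe). All 5 miRNAs of the HOX clusters detected on both arrays were higher (median 0.65), from miR-10b-5p (0.51 ± 0.018) and miR-10a-5p (0.54 ± 0.019) to miR-196b-5p and miR-10a-3p, while miR-10b-3p was detected on the vehicle-file array only. These medians kept their sign under the same 10 alternatives, the lowest being 0.36, 0.32 and 0.30.

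Other groups lay low on the inhibitor-file array. The 3 miRNAs of the intestinal epithelium, miR-192-5p (-0.89 ± 0.042), miR-215 (-0.85 ± 0.29) and miR-194-5p (-0.70 ± 0.050), were all lower, with a median of -0.85 at percentile 3.12 of random lists, within their 95% range. The list of p53-responsive miRNAs had a median of -0.70 (percentile 1.82), carried by the same 3 miRNAs, while miR-107 (0.60 ± 0.023) and miR-34a-5p (0.25 ± 0.043) were higher. The list of Wnt-related miRNAs had a median of -0.74 (percentile 1.96) over 4 members detected on both arrays, which went both ways: miR-4496 and miR-320a were over 2-fold lower, and miR-200a-3p (0.16 ± 0.017) and miR-34a-5p lay above 0. Of its other members miR-135a-3p was detected on the vehicle-file array only and miR-200a-5p on the inhibitor-file array only. That list included miR-4496 because of the study, so it is not independent evidence of a direction. Without the detection filter the medians were 0.22 over all 16 p53 members and 0.083 over all 12 Wnt members. Only 5 and 4 of these were detected on both arrays, and the median of all 2006 miRNAs was 0.12 in that setting. These 2 medians therefore do not show a reversal of the detected members. With normexp the p53 and Wnt medians were -0.086 and -0.38. With all spots required above background, where miR-4496 dropped out, the Wnt median was -0.014.

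The list of GC-rich miRNAs, drawn up beforehand as a possible sign of array background, was lower on the inhibitor-file array as well. Of its 33 members detected on both arrays 26 lay below 0, 4 of them at least 2-fold lower. Besides miR-5787 and miR-4530 those below 0 included its brightest members, miR-6089 (-0.14 ± 0.015) and miR-4516 (-0.16 ± 0.010). The list median of -0.18, at percentile 1.32, kept its sign under the 10 alternatives. Most of its members are numbered above 1000, a class with a median of -0.14 to which the random lists were not matched. The negative controls went the other way, at a mean of 1.96 on the vehicle-file array and 3.70 on the inhibitor-file array. The list therefore does not show a lower background there, and GC content was not examined. The 6 miRNAs annotated on fragments of other short RNAs went both ways (median -0.14, percentile 18.1; 0.13 with normexp), with miR-1246 and miR-1290 lower and miR-4286 (0.39 ± 0.0079) and miR-1260a (0.36 ± 0.015) higher.

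The remaining lists with at least 3 members detected on both arrays lay within the range of random lists. The miR-200 family, which maintains the epithelial state, had a median of 0.33 over 6 members (miR-141-3p 0.20 ± 0.015, miR-200b-3p 0.47 ± 0.022, miR-200b-5p 0.50 ± 0.098, miR-429 0.66 ± 0.021), which turned to -0.017 without scaling. The let-7 family had a median of 0.15 over 8 members (let-7a-5p -0.023 ± 0.019, let-7b-5p -0.42 ± 0.021, let-7c -0.36 ± 0.016), which turned to -0.20 without scaling. The medians were 0.43 for the miR-23/27/24 clusters (miR-27a-3p 0.81 ± 0.014, miR-24-3p 0.74 ± 0.017) and 0.45 for the miR-99, miR-100 and miR-125 clusters (miR-125b-1-3p 0.80 ± 0.061, miR-100-5p 0.54 ± 0.055, miR-125a-3p -0.43 ± 0.020, miR-99b-3p -0.24 ± 0.020). The medians of the miR-130 and miR-301 family (0.24, with miR-130b-3p 0.55 ± 0.033, miR-301a-3p 0.17 ± 0.034, and miR-301b 0.24 ± 0.072 from 1 probe) and of miRNAs reported higher in colorectal tumours (0.15, with miR-21-5p 0.58 ± 0.022, miR-96-5p 0.14 ± 0.022) turned to -0.11 and -0.20 without scaling. The miR-181 family had a median of -0.20 (miR-181a-5p -0.80 ± 0.021, miR-181b-5p -0.20 ± 0.028), and the miR-30 family of -0.052 (miR-30b-5p 0.21 ± 0.035, miR-30d-5p -0.16 ± 0.029), which turned to 0.025 with quantile normalization and 0.026 with the median as the scale. Of the 18 lists compared with random lists 7 lay outside the 95% range. Lists share members, family members are not independent and random lists were not matched on miRNA number, so no number expected by chance is given.

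Pairs and single miRNAs fixed in advance had no random lists. The cluster of miR-221 and miR-222 was split between miR-221-3p and miR-222-3p (0.012 ± 0.035, from 1 probe). Values were 0.91 ± 0.024 for miR-103a-3p, partner of miR-107, 0.26 ± 0.015 for miR-26a-5p, 0.23 ± 0.019 for miR-26b-5p, 0.44 ± 0.032 for the hypoxia-induced miR-210 and 0.32 ± 0.029 for miR-378a-3p, the 1 detected member of the miRNAs reported lower in colorectal tumours. Among markers of other cell types, 0 of 19 stromal, 0 of 2 endothelial and 0 of 2 liver miRNAs were detected on either array. Of 15 blood cell miRNAs 4 were detected (median -0.14, but 0.062 with normexp; miR-150-3p 0.17 ± 0.025, miR-146a-5p -0.29 ± 0.029, miR-155-5p -0.53 ± 0.059). Of 8 muscle miRNAs only miR-206 (0.32 ± 0.048) was detected, and of 11 neural miRNAs only miR-128 (0.44 ± 0.045). Of 15 pluripotent cell miRNAs 2 were detected, miR-371a-5p (-0.12 ± 0.024) and miR-373-5p (-0.098 ± 0.11, from 1 probe). The signals of miR-206 (26.4 and 25.9 on the vehicle-file and inhibitor-file arrays) and miR-373-5p (27.7 and 20.5) were dim. The dimmest detected probes had 15.7 and 15.9. Members of a family differ by few bases, so their probes can share signal and family members are not independent of each other.

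**Figure D3:**
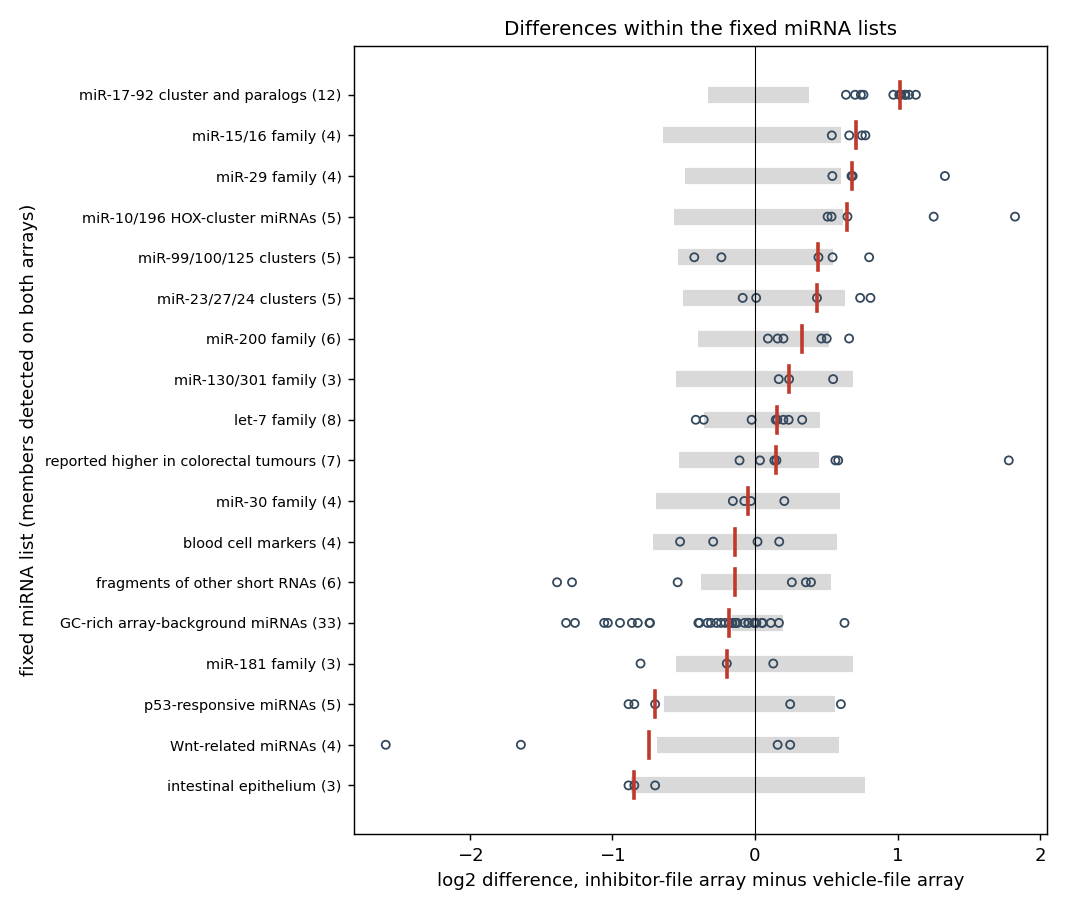
Log2 difference (inhibitor-file array minus vehicle-file array) of each miRNA detected on both arrays, for the 18 fixed lists with at least 3 such members; circles are single miRNAs, red bars list medians, and grey bands hold the medians of 95% of 10000 random lists of the same size matched on signal. The miR-17-92 list, with a median of 1.01, lies farthest above its band, and the Wnt, p53 and GC-rich lists lie just below theirs.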

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

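The tests of an exchange of labels and of its place, of RNA fragments, and of brightness and cross-hybridisation in the miR-17-92 list were chosen after the result was seen. Signals outside the main measurement came from the positive control probes of the array, whose signal stood above the 99th percentile of the negative controls on both arrays (10.3 and 12.3). Their median processed signals on the vehicle-file and inhibitor-file arrays were 211000 and 262000 for hur_1, 168500 and 227000 for hur_2, 8495 and 9500 for hur_4, 171.5 and 231 for hur_5, 13950 and 17900 for hur_6, 13050 and 12850 for mr_1, and 30.25 and 54.3 for the bright corner spots. What the hur and mr probes detect is not stated in the sources used here. The 5 hur probes were brighter on the inhibitor-file array by 0.16 to 0.43 on the log2 scale before scaling, while the miRNA probes were dimmer there by 0.35 at the 75th percentile. After the main scaling the hur probes stood 0.51 to 0.78 higher there, mr_1 0.33 and the bright corner spots 1.19. The medians of the miR-15/16, miR-29 and HOX cluster lists (0.65 to 0.71) lie within the range of the hur probes. So do miR-25-3p (0.64), miR-106b-5p (0.70), miR-92a-3p (0.74) and miR-93-5p (0.76) of the miR-17-92 list. Its other members detected on both arrays and its median of 1.01 lie above that range. No setting scaled the arrays on these probes.

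The first pattern is the crossing of labels. An exchange of labels in 1 of the 2 sources may account for it. The match of 2006 of 2006 values to the other sample's file is the crossing itself, so it is no separate test of this. A single array deposited under both names is argued against by the spots, of which 0.123% have the same processed signal in both files. Whether the scanner files or the value table are exchanged cannot be told apart: the shared statistics block states 11411 spots well above background, which describes the vehicle file but names no condition. The study's account of miR-4496 goes with the value table, but a direction read from an outcome does not settle a label.

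The second pattern is that late-numbered miRNAs lay lower on the inhibitor-file array than early ones. Of the 365 miRNAs detected on both arrays, the 193 numbered above 1000 had a median of -0.14 and the 172 others 0.21, a gap of -0.35. Of the miRNAs detected on 1 array only, 41 of the 62 on the vehicle-file array were late-numbered, against 2 of the 15 on the other array. The late-numbered share of all miRNAs on the array was not computed, so these counts are not read as an enrichment. A trend with brightness is argued against: the gap kept its sign in all 5 signal bins, with a median of -0.34. A difference in RNA quality or in fragments of other RNAs stays open, because the fragment list had a median of -0.14 with members going both ways, and so does the treatment, which was not replicated.

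The third pattern is the joint shift of the miR-17-92 cluster and its paralogs, where a trend with brightness is argued against because the medians of 95% of matched random lists reached 0.38 at most and the list stood at 1.01. Cross-hybridisation between members stays open, although the miR-17, miR-18, miR-19 and miR-92/25 sequence families all stood high, with medians of 1.01, 1.05, 1.04 and 0.69. With each family counted as 1 observation, 10 of 10000 random draws of single miRNAs had as high a median over the 4 families, and 89 of 10000 as high as 1.01 when the more alike miR-17 and miR-18 families were merged; the list was the farthest out of 18, and probe sequences were not available. This test replaced a bound set beforehand, each family above the range of single miRNAs, which was not met. The treatment is also open as a cause, in either direction, since each condition has 1 array.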

How the results depend on the processing

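Normexp on the median signal and the value table matched to the scanner files were chosen after the result was seen. No paired analysis was possible because each condition has 1 array. A slide or replicate block could not be fitted for the same reason, and normexp on the mean signal was not run because that column is absent. Under the alternatives that keep the scanner labels and differ by more than a single factor common to all miRNAs, none of the 17 higher and 19 lower miRNAs that remained detected on both arrays changed sign. Under all 10 that keep these labels miR-4496 lay between -2.94 and -0.91. Of 877 values of the other named miRNAs, 567 moved by less than 1 SD between spots and 310 by more. Signal over background limits dim miRNAs such as miR-4496, whose level on the inhibitor-file array lay at the detection limit.

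The counts at least 2-fold higher and lower on the inhibitor-file array (17 and 19) became 4 and 5 with normexp, where miR-4496 was at -0.91, 11 and 22 with the 75th percentile of all probes, and 4 and 40 without scaling. They were 8 and 26 with all spots required above background, 37 and 54 without a detection filter, which leaves 0 miRNAs on 1 array only, and 24 and 32 with the scaled total gene signal. The value table gave 62 higher and 13 lower with the inhibitor by its column names, and 13 and 62 matched to the scanner files. Without scaling all 18 list medians moved by -0.35, the scale factor left out, and with all spots above background 12 of 17 moved by -0.17, the change of the scale factor. For the other settings the cause of a list median that moved by more than the SD of its members or changed sign was not tested. With normexp the medians were 0.72 for the miR-17-92 cluster, 0.53 for the miR-15/16 family, -0.32 for the intestinal epithelium and 0.13 for the miR-30 family. Without scaling they were -0.20 for the let-7 family, -0.017 for the miR-200 family, 0.67 for the miR-17-92 cluster, 0.36 for the miR-15/16 family, -1.20 for the intestinal epithelium, -0.40 for the miR-30 family, -0.11 for the miR-130 and miR-301 family and -0.49 for the blood cell markers. With all spots above background they were 0.84 for the miR-17-92 cluster, 0.53 for the miR-15/16 family and -1.02 for the intestinal epithelium. Without a detection filter the medians cover every list member on the array, also the undetected ones. They were then 0.70 for the miR-17-92 cluster, 0.54 for the miR-15/16 family, -0.70 for the intestinal epithelium, 0.22 for the p53-responsive miRNAs, 0.083 for the Wnt-related miRNAs and 0.21 for the miR-30 family. With the value table matched to the scanner files they were -0.19 for the let-7 family, 0.060 for the miR-200 family, 0.67 for the miR-17-92 cluster, 0.41 for the miR-15/16 family, -1.22 for the intestinal epithelium, 0.32 for the miR-29 family, -0.33 for the miR-30 family, -0.14 for the miR-130 and miR-301 family, -0.74 for the miR-181 family and -0.47 for the blood cell markers.

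By the column names of the value table the list medians were -0.060 for the miR-200 family, -0.67 for the miR-17-92 cluster, -0.41 for the miR-15/16 family, 1.22 for the intestinal epithelium, 1.03 for the p53-responsive miRNAs, 1.07 for the Wnt-related miRNAs, -0.32 for the miR-29 family, 0.33 for the miR-30 family, -0.074 for the miR-23/27/24 clusters, -0.11 for the miR-99, miR-100 and miR-125 clusters, 0.74 for the miR-181 family, -0.30 for the HOX cluster miRNAs, 0.47 for the blood cell markers and 0.61 for the GC-rich array-background miRNAs, since its columns are crossed. As this table is unscaled, some lists kept their sign, at 0.19 for the let-7 family, 0.14 for the miR-130 and miR-301 family and 0.0072 for the miRNAs reported higher in colorectal tumours. The difference of miR-4496 was then 2.92. All other named miRNAs at least 2-fold apart or with a bound changed sign. Among them (inhibitor minus vehicle, unscaled log2, with bounds for miR-658 and miR-424-3p) those above 0 were at 2.91 for miR-4497, 1.98 for miR-320a, 1.83 for miR-630, 1.80 for miR-4459, 1.75 for miR-513a-5p, 1.73 for miR-575, 1.75 for miR-1246, 1.86 for miR-6126, 1.68 for miR-5787, 1.71 for miR-1290, 1.60 for miR-4530, 3.45 for miR-1287, 4.19 for miR-658, 3.59 for miR-424-3p and 1.93 for miR-5703. Those below 0 were at -1.51 for miR-10a-3p, -1.43 for miR-21-3p, -1.43 for miR-7-5p, -1.06 for miR-3934-5p, -1.39 for miR-29b-1-5p, -0.86 for miR-221-3p, -0.89 for miR-196b-5p, -0.81 for miR-622, -0.82 for miR-3135b, -0.79 for miR-18a-5p, -0.77 for miR-5585-3p, -0.74 for miR-17-5p, -0.74 for miR-193a-3p, -1.05 for miR-149-5p, -1.04 for miR-16-2-3p, -1.63 for miR-141-5p, -0.66 for miR-19b-3p and -0.67 for miR-20a-5p.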

Other observations

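The comparison without pairs inside the miR-17-92 list, the reading of the arm test and the genes named here were chosen after the result was seen. Genes that neighbour each other in the genome differed between the arrays by similar amounts on average. The MIR25, MIR93 and MIR106B genes gave 0.64, 0.76 and 0.70 on the log2 scale, and MIR193B and MIR365A gave 0.69 and 0.56. On the X chromosome MIR532 gave 0.43 (miR-532-5p), MIR362 0.38 and 0.29 (miR-362-3p and miR-362-5p) and MIR660 0.45 (miR-660-5p). MIR188 beside them gave -0.14. MIR221 and MIR222 (1.26 and 0.012), MIR27A and MIR23A (0.81 and 0.0084) and MIR4745 and MIR3187 (-1.02 and 0.0056) did not go together. Nor did MIR27B and MIR23B (0.43 and -0.086) or MIR487B and MIR134 (0.46 and -0.14). The hypothesis that miRNAs of a cluster follow a shared transcript was tested on 47 pairs of miRNAs from neighbouring genes with different miRNA numbers. They came from 52 miRNAs in 19 clusters, in which each gene starts within 10 kb of the one before. Where both arms of a gene were detected, each was paired with the same neighbours, so pairs outnumber gene pairs. Strand was not used. The mean absolute gap of the 47 pairs was 0.26, against a 95% range of 0.45 to 0.82 in 10000 shuffles within signal bins, and 0 shuffles were as low. Without pairs inside the miR-17-92 list 34 pairs remained, with a mean gap of 0.34 against 0.42 to 0.83. These data leave shared transcription as a candidate explanation, as far as 1 array per condition goes. Pairs with different numbers can still belong to 1 family, as miR-130b-3p and miR-301b do, and such pairs stayed in both comparisons. Signal shared between the probes of like sequences therefore stays open too, and miRNAs are not independent replicates.

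The arms of one precursor were compared in the same way. In 19 precursors with both arms detected, the mean absolute gap was 0.44, at the lower edge of the 95% range of shuffles (0.42 to 0.86), which leaves open whether arms follow 1 precursor level. The bound written beforehand counted any gap inside the range against the hypothesis; that reading was dropped after the value was seen, since a gap inside the range excludes nothing. The arms of miR-21 (0.58 for -5p, 1.78 for -3p), miR-10a (0.54 and 1.82) and miR-3162 (-1.06 for -5p, -0.046 for -3p) were the farthest apart.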
